A study of Drosophila melanogaster with 12 samples.

How the data were processed

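Total RNA of wing discs from 12 samples in 3 groups of 4 was sequenced. Per the labels' protocols, RNA of 150 discs per sample was extracted with TRI Reagent and treated with DNase, and libraries were made with a stranded kit that removes ribosomal RNA. The labels differ on the run: the series' design text names single reads on one Illumina model and the extract protocol paired reads on another, so the read layout is not taken as known here. Groups and replicate numbers were taken from the sample titles.

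The main values are the authors' deposited normalized counts, a signal per gene that is never negative and is on a common scale for the 12 libraries. Per the labels they are DESeq2-normalized counts made by the authors. The submitters' processing notes name FastQC, cutadapt 3.5, kallisto 0.46.1, DESeq2 1.34.0 and genome build BDGP6 with no order or settings, and whether counting used strand is not given in the sources used here. With stranded libraries and no stated setting, values of genes that overlap on opposite strands are uncertain, as are those of near-identical copies. Raw counts were not used here. The smallest steps between low values were compared with whole reads: 50.6% to 82.1% of low values per library came out whole within a tolerance of 0.03, too few to recover reads, so no count model was fitted and the depth of 26.8 to 37.6 M reads per library is an estimate. Counting error is thus not modelled on its own, and the precision of each value is that of the spread between the 4 libraries.

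A second table holds the authors' own comparisons of the groups. Per the file headers, it gives log2 fold changes with standard errors, a test statistic as a score, and p-values with adjusted p-values from DESeq2, run by the authors. Its counts of genes and its adjusted p are printed as values of the authors' deposited table. Another table holds intron retention. Per the file headers, the authors give for each intron a retention ratio as a fraction from 0 to 1, as the mean of each group, with log2 fold changes and adjusted p-values from DESeq2 by the authors. The tool that called the ratios is not given in the sources used here. That table's 12 columns of ratios per sample carry names that could not be tied to the labels and were not used, so no test between replicates was run on introns. All 17817 introns matched introns of the BDGP6 annotation (Ensembl), from which gene positions were taken, and coordinates are 1-based.

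The expression table held 23932 rows, of which 17869 carry a gene ID and 6063 are transposable elements or other features. Symbols were found for 17789 gene IDs and positions for 17790. Rows that are not genes took 0.452% to 7.40% of the signal per library and stayed out of the tests. Of the tested genes, 268 have a row identical to that of another gene, and an alternative left them out. Values were transformed as log2(value + 1), which understates the change of low genes, and genes with a mean of at least 10 over the 12 libraries entered, 10179 in all. Linear models with a term per group were fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), tests were two-sided, p was adjusted by the method of Benjamini and Hochberg, and a gene passed at an adjusted p under 0.05. Every adjusted p not credited to the authors' deposited table is from limma. Exact values of 0 occur for genes that cells commonly use, so a gene at 0 in a whole group is described as listed at 0, with each library's value and no fold change.

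The named genes were chosen by a fixed rule. They are 14 focus genes (ecd, Xrp1, Irbp18, Prp8, Ilp8, crc, rpr, hid, puc, Mmp1, upd3, Gadd45, p53 and nub), the 5 largest rises and 5 largest falls among genes that passed with a mean of at least 50 and no overlap of the groups, up to 2 members of each list that rose and 2 that fell most, the 5 introns that rose and the 5 that fell most by ratio, and the 5 largest reversed and 5 largest not significantly shifted changes. A part of these is described. Lsp2 and Fbp1, used to describe fat body, were chosen after their values were seen. Lists of genes, 34 in all, were written from general knowledge of stress pathways, complexes and cell types of the disc; 11 of their symbols matched no gene of the table. They were tested with camera at the preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 34 lists. The Xrp1-associated list holds genes tied to Xrp1 in general knowledge, which can include this study's own.

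A gene was counted as reversed when it passed with ecd RNAi against control and passed in the opposite direction with ecd plus Xrp1 RNAi against ecd RNAi. The share removed is the difference between the RNAi groups as a percent of the ecd RNAi change. Both measures were repeated with the ecd RNAi libraries split into 2 and 2 and on 20 simulated data sets with no reversal. Overlap of introns and expression was tested with Fisher's exact test, two-sided. The limma step was tested on simulated data for ecd RNAi against control, over 10179 genes with 200 changed: 47.0%, 77.6% and 88.1% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 4 false calls (2.74%) and median estimates of 0.50, 0.98 and 2.01.

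Replicate numbers are shared by the groups, so it was checked whether they pair the samples. Deviations from the group means of samples with the same title number correlated between control and ecd RNAi by 0.53, 0.41, 0.56 and 0.24, each above 0.1, which by the fixed rule counts as pairing for this comparison. Each control sample correlated best with another number of ecd RNAi, however, 1 with 2, 2 with 1, 3 with 4 and 4 with 3. The labels name no shared day or batch. The other pairs of groups gave -0.35 to -0.13 and were not paired. Alternatives were other pseudocounts and filters on low values, recomputed TMM factors, quantile normalization, fits of the compared groups alone, array weights, robust empirical Bayes, replicate blocks, leaving out each library, the authors' deposited adjusted p and a 2-fold minimum. Added after the data were seen were fits without the 4 libraries rich in fat body transcripts, with all rows, without identical copies, and of replicates 1 and 2 or 3 and 4 alone. Other work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and statmod 1.5.0.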

Results

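Gene expression was measured by sequencing total RNA, after depletion of ribosomal RNA, from wing imaginal discs of Drosophila melanogaster. These discs are the epithelial sacs of the larva that form the adult wing and part of the thorax. Each of the 12 samples pooled 150 discs taken from L3 larvae at 7 days after the eggs were laid. Transgenes were expressed with nub-Gal4, a driver active in the domain of the gene nubbin, which covers the wing pouch at the centre of the disc, and the discs also held tissue outside this domain. The samples formed 3 groups of 4, called biological replicates in the labels. Control discs carried the driver and a red fluorescent reporter, the second group is labelled with RNAi against ecd in addition, and the third with RNAi against both ecd and Xrp1. The gene ecd (ecdysoneless) encodes a protein that acts with Prp8, a core protein of the spliceosome, and Xrp1 encodes a stress-induced transcription factor of the bZIP class that pairs with Irbp18. The series concerns the response to a failing spliceosome. The comparisons thus ask which transcripts change with ecd RNAi and which of these changes shift when Xrp1 RNAi is added. No group with Xrp1 RNAi alone was analysed here.

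Normalized counts summed to 26500844 to 28994135 per control library, 32368922 to 35397850 per library labelled ecd RNAi and 29133078 to 32260828 per library labelled ecd plus Xrp1 RNAi. The steps between low values put the depth at about 26.8 to 37.6 M reads per library. Rows of ribosomal RNA took 16.6% to 19.8% of the signal in the controls, 20.3% to 28.7% with ecd RNAi and 20.2% to 28.7% with ecd plus Xrp1 RNAi. Log2 values correlated between replicates with r of 0.944 to 0.984 in the controls, 0.941 to 0.980 with ecd RNAi and 0.976 to 0.985 with ecd plus Xrp1 RNAi. Larval serum protein Lsp2, an abundant product of fat body, stood at 194, 1594, 17176 and 6826 normalized counts in control replicates 1 to 4, at 688, 263, 5585 and 5649 with ecd RNAi and at 833, 455, 679 and 559 with ecd plus Xrp1 RNAi. Control replicates 3 and 4 and ecd RNAi replicates 3 and 4 are called the 4 libraries rich in fat body transcripts below. Levels below are given as mean normalized counts ± SD over the 4 libraries of a group, and changes as log2 fold changes ± SE on the log2(value + 1) scale, with adjusted p from limma over 10179 genes.

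The targeted genes were examined first. Transcripts of ecd (FBgn0000543, chromosome 3L, 2263581 to 2265857, genome build BDGP6) stood at 1654, 1494, 1421 and 1420.3 normalized counts in control replicates 1 to 4, at 1982, 1687, 1423 and 1521 in the libraries labelled ecd RNAi, and at 1825, 1766, 1696 and 1699 in the libraries labelled ecd plus Xrp1 RNAi. The ecd transcript was thus not lower in the libraries labelled ecd RNAi than in control (log2 fold change 0.13 ± 0.09, adjusted p = 0.251), and these values give no check of that label. Under quantile normalization and under array weights ecd passed as higher, with changes of 0.17 and 0.22 and adjusted p of 0.0492 and 0.0353 in a range of 0.0353 to 0.68 over the alternatives. Every direction drawn below for ecd RNAi therefore rests on the label. Xrp1 (FBgn0261113, chromosome 3R, 18914968 to 18926989) stood at 4709.5, 4511, 4949 and 5078 in the controls, at 22964, 20019, 21561 and 18985 with ecd RNAi and at 4447, 4474, 5365 and 6048 with ecd plus Xrp1 RNAi.

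Which transcripts changed with ecd RNAi was asked by comparing the libraries labelled ecd RNAi with control. Xrp1 rose from 4812 ± 252 (SD, n = 4) to 20880 ± 1745, a log2 change of 2.12 ± 0.10 (adjusted p = 3.5e-09). Irbp18, its dimer partner (FBgn0036126, chromosome 3L, 11097446 to 11098186), rose by 1.98 ± 0.10 (adjusted p = 7.9e-09). Ilp8, the insulin-like peptide with which damaged discs delay pupariation (FBgn0036690, chromosome 3L, 17029812 to 17032080), rose from 35.7 ± 19.8 (SD, n = 4) to 8434 ± 842 (adjusted p = 5.1e-09). The cytokine upd3 (FBgn0053542, chromosome X, 18277233 to 18284596) rose from 23.4 ± 5.81 (SD, n = 4) to 1480 ± 67.3 (adjusted p = 1.5e-10). The capsid-like gene Arc1 (FBgn0033926, chromosome 2R, 14357927 to 14360297) rose from 1642 ± 318 (SD, n = 4) to 286700 ± 23250 (adjusted p = 1.3e-12). Hr3 and ImpE2, genes induced by the steroid hormone ecdysone, fell.

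In all, 4867 of 10179 tested genes passed an adjusted p of 0.05 in limma, 2280 higher and 2587 lower, and 1237 of them changed at least 2-fold, 797 higher and 440 lower. The values of the 2 groups did not overlap for 4555 genes, where chance gives 2.86%. The authors' deposited table lists 5069 gene rows past the same threshold, 2450 higher and 2619 lower. Without the 4 libraries rich in fat body transcripts, an alternative chosen after seeing the data, the fit called 4090 genes, with the filter on the mean applied to the 8 libraries left.

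Among genes with larger rises was CG8620, which went from 1.93 ± 0.678 (SD, n = 4) to 2121 ± 568 (adjusted p = 1.1e-10), and the dopamine receptor gene Dop2R, from 4.10 ± 1.36 (SD, n = 4) to 2122 ± 1095 (adjusted p = 3.9e-09). CG14304 was listed at 0 in every control and at 1766, 1549.6, 1511 and 1065 with ecd RNAi. The chemokine-like gene orion was listed at 0 in every control and at 802, 607, 514 and 765 with ecd RNAi, and the transferrin gene Tsf3 likewise at 0 and then at 549, 515, 638 and 548. Genes with larger falls included aos (argos), a secreted inhibitor of EGF receptor signalling, which stood at 391.97, 314, 254 and 264 in the controls and was listed at 0 in every library labelled ecd RNAi. Pbp45 stood at 117, 111, 126 and 155 in the controls and was listed at 0 with ecd RNAi. The antisense RNA asRNA:bsAS (FBgn0266046, chromosome 2R, 24351477 to 24369689) stood at 1225, 1342, 1133 and 1239 and was also listed at 0 with ecd RNAi. It lies across bs (blistered, FBgn0004101, chromosome 2R, 24342861 to 24376473), a transcription factor of intervein cells that fell by 2.09 ± 0.11 (adjusted p = 7.9e-09). Whether counting used strand is not given in the sources used here, so reads of the pair cannot be told apart. CR43482 stood at 907, 790.2, 563 and 422 and then at 0, 0, 0 and 173, and fok (fledgling of Klp38B) at 416, 488, 505 and 435 and then at 0, 0, 0 and 127. These falls passed here, with adjusted p of 0.00603 and 3.9e-04, but not in the authors' deposited table, which gives adjusted p of 0.156 and 0.0507, nor in replicates 3 and 4 alone, where adjusted p was 0.177 and 0.148. Over all alternatives adjusted p ran from 9.6e-05 to 0.177 for CR43482 and from 8.4e-10 to 0.148 for fok.

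**Figure D1:**
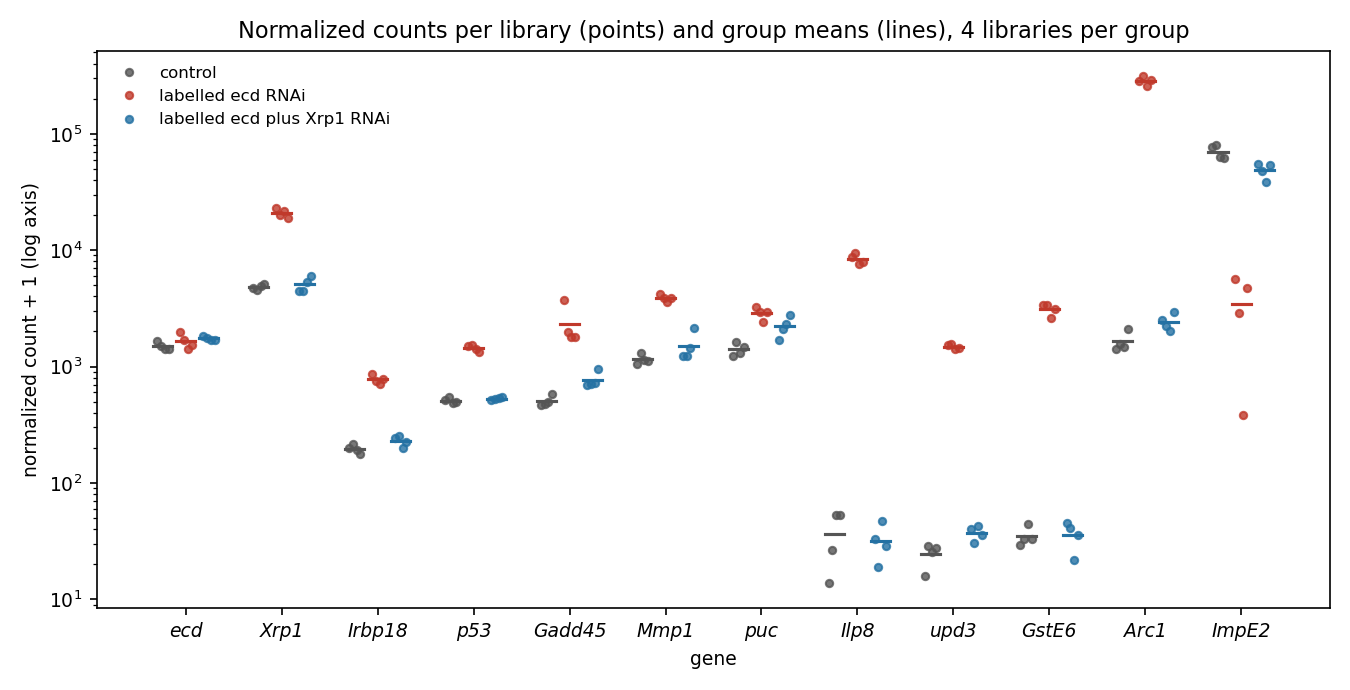
Normalized counts of 12 genes in each of the 12 libraries (points, log axis), with a line at each group's mean. The ecd transcript lay at a like level in the 3 groups, while Xrp1, Irbp18, p53, Ilp8, upd3, GstE6 and Arc1 stood above every control in all 4 libraries labelled ecd RNAi, and ImpE2 below every control.

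Stress genes made up several of the lists fixed before the data were examined. Of 10 measured Xrp1-associated genes, 9 rose and 0 fell over all genes tested and 9 rose adjusted over the list alone; the list passed camera (adjusted p = 1.2e-07; adjusted p = 0.150 with an estimated correlation). The list of DNA damage response and repair genes held 20 that rose and 3 that fell among 27, and as many adjusted over the list alone (camera adjusted p = 1.2e-07; adjusted p = 0.373 with an estimated correlation). In it p53, the transcription factor of the DNA damage response (FBgn0039044, chromosome 3R, 23049657 to 23054082), rose from 507 ± 27.4 (SD, n = 4) to 1441 ± 97.9 (adjusted p = 2.0e-09) and Gadd45 rose by 2.14 ± 0.20 (adjusted p = 2.4e-06). Corp, a regulator of p53, was listed at 0 in the controls and at 242, 89.2, 69.0 and 108 with ecd RNAi. The checkpoint kinase gene grp fell by 0.77 ± 0.07 (adjusted p = 1.5e-06). In the list of the JNK pathway and its targets, 14 rose and 3 fell of 21, and 15 rose and 3 fell adjusted over the list alone (camera adjusted p = 4.0e-06; adjusted p = 0.406 with an estimated correlation). The transcription factor gene Ets21C rose from 27.9 ± 7.42 (SD, n = 4) to 2106 ± 219 (adjusted p = 2.6e-07), the matrix metalloproteinase gene Mmp1 rose by 1.76 ± 0.15 (adjusted p = 8.0e-07) and the JNK phosphatase gene puc by 1.04 ± 0.14 (adjusted p = 5.2e-05). Of 11 measured JAK/STAT genes, 8 rose and 0 fell, and 8 rose adjusted over the list alone (camera adjusted p = 2.2e-06; adjusted p = 0.287 with an estimated correlation). The cytokine upd2 rose by 6.16 ± 0.39 (adjusted p = 6.8e-08). The cytokine genes of the upd family stand in both the JNK and the JAK/STAT list. The Xrp1-associated list holds p53, GstE6, rpr, hid, crc and Thor, which are also described with other lists. Calls of lists that share members are not separate results.

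Among 27 glutathione S-transferase genes, which encode detoxifying enzymes, 15 rose and 7 fell, with like counts adjusted over the list alone (camera adjusted p = 0.0179; adjusted p = 0.370 with an estimated correlation). GstE6 rose from 33.9 ± 6.50 (SD, n = 4) to 3131 ± 356 (adjusted p = 2.2e-10), while GstE11 fell by 0.88 ± 0.09 (adjusted p = 3.1e-06). Of 21 other redox and detoxification enzymes 6 rose and 5 fell (camera adjusted p = 0.968), with the malic enzyme gene Men up by 1.91 ± 0.14 (adjusted p = 2.9e-07) and the catalase gene Cat down, having fallen by 1.06 ± 0.10 (adjusted p = 2.0e-06). The autophagy list held 11 that rose and 2 that fell of 21, the same adjusted over the list alone (camera adjusted p = 0.0248; adjusted p = 0.832 with an estimated correlation). The receptor gene ref(2)P rose by 1.24 ± 0.08 (adjusted p = 1.1e-07). Of 14 apoptosis genes 5 rose and 3 fell (camera adjusted p = 0.529). The caspase activator rpr rose by 0.59 ± 0.10 (adjusted p = 3.1e-04) and egr, a TNF ligand, rose by 1.17 ± 0.16 (adjusted p = 6.2e-05). For hid the change was 0.10 (adjusted p = 0.320), a value called under quantile normalization alone, at 0.18 and adjusted p = 0.0184 in a range of 0.0184 to 0.649 over the alternatives. Among 16 genes of the integrated stress response and amino acid supply 8 rose and 5 fell (camera adjusted p = 0.209). The transcription factor genes Atf3 and crc, the fly ATF4, rose by 2.41 ± 0.18 and 0.70 ± 0.07 (adjusted p = 2.5e-07 and 6.1e-06) and the translation inhibitor gene Thor by 3.43 ± 0.42 (adjusted p = 2.2e-05). CG6287, a phosphoglycerate dehydrogenase of serine synthesis, fell from 4003 ± 348 (SD, n = 4) to 632 ± 242 (adjusted p = 8.9e-07).

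Of 32 proteasome subunit genes, 31 fell and 0 rose, and all 32 fell adjusted over the list alone (camera adjusted p = 7.8e-12; adjusted p = 0.664 with an estimated correlation). Rpt2 fell from 5455 ± 482 (SD, n = 4) to 2950 ± 316 (adjusted p = 1.9e-06). Of 20 genes of the unfolded protein response of the endoplasmic reticulum 15 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 1.2e-04; adjusted p = 0.832 with an estimated correlation). The disulfide isomerase gene Pdi fell by 1.26 ± 0.12 (adjusted p = 2.8e-06) and the translocon gene Sec61alpha fell by 1.32 ± 0.11 (adjusted p = 9.8e-07), and the sensor gene Ire1 rose by 0.29 ± 0.07 (adjusted p = 0.00359). Among 20 heat shock protein genes 7 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.0179; adjusted p = 0.842 with an estimated correlation). Hsp27, a small chaperone, fell from 35090 ± 4945 (SD, n = 4) to 7697 ± 2204 (adjusted p = 1.1e-06). Of 33 oxidative phosphorylation genes 29 fell and 0 rose, and 31 fell adjusted over the list alone (camera adjusted p = 9.3e-09; adjusted p = 0.684 with an estimated correlation), COX8 among them with a change of -0.95 (adjusted p = 1.4e-05). Of 13 glycolysis and lactate genes 4 rose and 2 fell (camera adjusted p = 0.505). The lactate dehydrogenase gene Ldh rose by 3.01 ± 0.35 (adjusted p = 1.6e-05).

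Of 45 spliceosome genes 27 fell and 6 rose, and 29 fell and 6 rose adjusted over the list alone (camera adjusted p = 2.9e-03; adjusted p = 0.842 with an estimated correlation). Prp31, a protein of the U4/U6 particle, rose by 1.04 ± 0.07 (adjusted p = 8.3e-08) and the helicase gene Brr2 by 0.68 ± 0.07 (adjusted p = 6.9e-06). SmD3, a core snRNP protein, stood at 272, 260.4, 143 and 249.9 in the controls and at 24.4, 29.6, 0 and 0 with ecd RNAi. Prp8 (FBgn0033688, chromosome 2R, 12154258 to 12162998) averaged 12380 ± 431 (SD, n = 4) and 11400 ± 1145 and did not pass (adjusted p = 0.212). Of 8 genes of nonsense-mediated decay, a list that also holds its known targets Gadd45 and Arc1, 4 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.0186; adjusted p = 0.684 with an estimated correlation). Among 79 ribosomal protein genes 3 rose and 1 fell, and 1 rose adjusted over the list alone (camera adjusted p = 0.180). Ribosome biogenesis genes held 4 that rose and 10 that fell of 22 (camera adjusted p = 0.209). Nop56 fell by 0.83 ± 0.07 (adjusted p = 1.6e-06). Cell cycle and DNA replication genes held 5 that rose and 15 that fell of 40 (camera adjusted p = 0.0664). Cdk1 fell by 0.78 ± 0.10 (adjusted p = 4.4e-05) while stg, the Cdc25 phosphatase, rose by 0.66 ± 0.09 (adjusted p = 3.8e-05).

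Ecdysone response genes moved in both directions, with 6 that rose and 10 that fell of 20 (camera adjusted p = 0.269). The nuclear receptor gene Hr3 fell from 1017 ± 203 (SD, n = 4) to 11.9 ± 10.3 (adjusted p = 5.2e-07) and ImpE2 from 70310 ± 9375 (SD, n = 4) to 3431 ± 2339 (adjusted p = 3.3e-05). ftz-f1, expressed after the hormone pulse, rose by 3.36 ± 0.17 (adjusted p = 6.7e-09). Fat body markers, which differ between libraries of both groups, held 1 that rose and 2 that fell of 12 (camera adjusted p = 0.968). Wing pouch markers held 2 that rose and 8 that fell of 12, the same adjusted over the list alone (camera adjusted p = 0.0315; adjusted p = 0.832 with an estimated correlation). sens (senseless), a factor of sensory organ precursors, fell by 3.18 ± 0.21 (adjusted p = 8.4e-08). The driver's own gene nub changed by -0.32 (adjusted p = 0.0303), and this call ended without control replicate 1, 2 or 4 or without ecd RNAi replicate 3 or 4, where adjusted p was 0.0511 to 0.0737. Adult muscle precursor markers held 6 that fell and 0 that rose of 10, the same adjusted over the list alone (camera adjusted p = 0.0281; adjusted p = 0.501 with an estimated correlation), among them kon, which fell by 0.61 ± 0.08 (adjusted p = 3.7e-05). Notum markers held 4 that fell of 8 (camera adjusted p = 0.0977), hinge markers 2 that rose and 2 that fell of 8 (adjusted p = 0.694) and peripodial markers 2 and 4 of 8 (adjusted p = 0.505). Hemocyte markers held 4 that rose and 6 that fell of 16 (adjusted p = 0.968), tracheal markers 4 and 4 of 10 (adjusted p = 0.938) and glial markers 2 and 1 of 6 (adjusted p = 0.505). No neuronal marker of 8 passed at an adjusted p in limma (camera adjusted p = 0.968). Patterning genes of the Wnt, Dpp, Hedgehog and Notch pathways held 7 that rose and 11 that fell of 32 (camera adjusted p = 0.212). Hippo pathway targets held 7 that rose and 2 that fell of 15 (adjusted p = 0.196), innate immunity genes 4 and 1 of 10 (adjusted p = 0.180) and cytoskeleton and adhesion genes 7 and 5 of 22 (adjusted p = 0.968). The innate immunity factor gene Dif rose by 5.16 ± 0.26 (adjusted p = 8.0e-09).

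Camera with its preset correlation called 14 of 34 lists in this comparison, 7 higher and 7 lower, and with an estimated correlation it called 0. The median, the mean and the direction of the test differed in sign for the redox, tracheal, neuronal, glial, innate immunity and cytoskeleton lists, none of which passed. In a fit of replicates 3 and 4 alone, an alternative chosen after seeing the data, the calls of rpr and Ire1 ended, with adjusted p of 0.0726 and 0.0676 in ranges over the alternatives of 8.5e-07 to 0.0726 and 5.3e-04 to 0.0676.

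**Figure D2:**
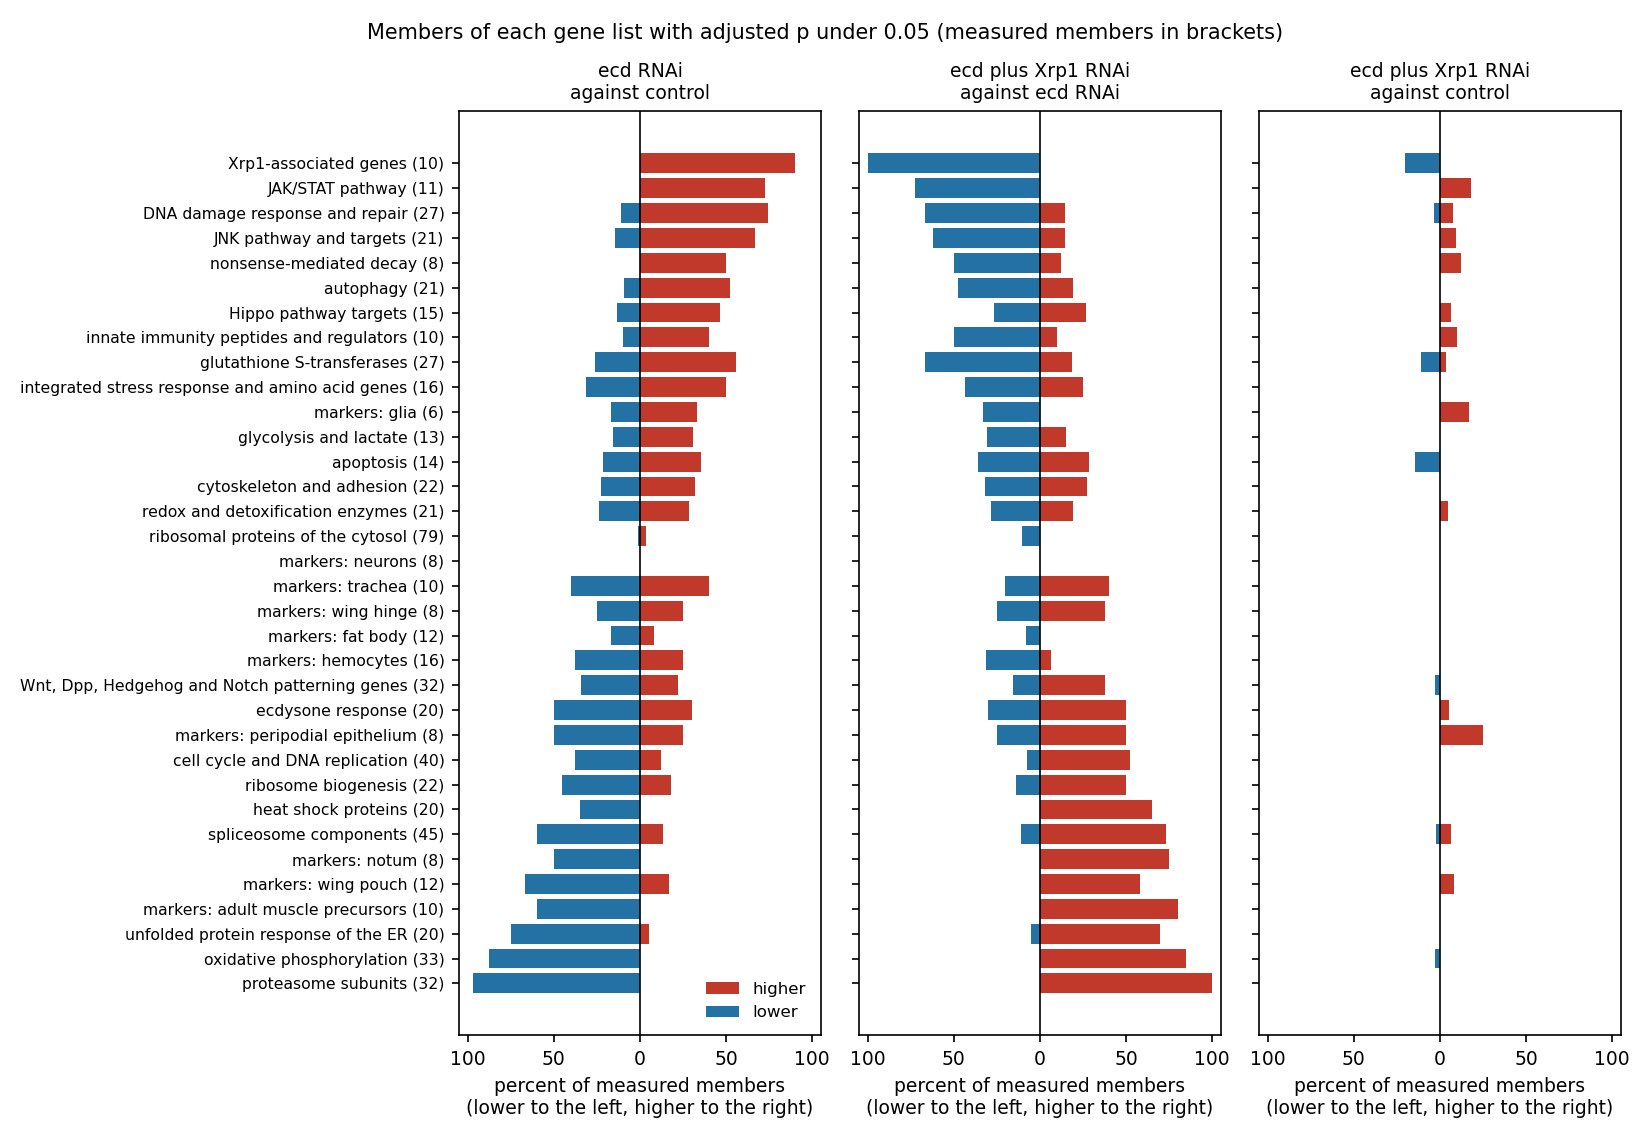
Percent of the measured members of each of the 34 gene lists that passed as higher or lower at an adjusted p of 0.05 in limma, in the 3 comparisons. Proteasome, oxidative phosphorylation and endoplasmic reticulum lists lie on the lower side with ecd RNAi against control and on the higher side with ecd plus Xrp1 RNAi against ecd RNAi, and few members of any list pass with ecd plus Xrp1 RNAi against control.

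Which of these differences shift with added Xrp1 RNAi was asked by comparing the libraries labelled ecd plus Xrp1 RNAi with those labelled ecd RNAi. The ecd transcript was not lower than control in either RNAi group. Whether ecd RNAi acted equally in both could thus not be checked, and a shift is not by itself dependence on Xrp1. Xrp1 itself fell by 2.05 ± 0.10 (adjusted p = 5.7e-09), from 20880 ± 1745 (SD, n = 4) to 5084 ± 772, and Irbp18 fell by 1.76 ± 0.10 (adjusted p = 2.8e-08). Ilp8 fell from 8434 ± 842 (SD, n = 4) to 30.9 ± 11.7 (adjusted p = 5.6e-09), upd3 from 1480 ± 67.3 (SD, n = 4) to 36.2 ± 5.45 (adjusted p = 5.4e-10) and Arc1 from 286700 ± 23250 (SD, n = 4) to 2429 ± 417 (adjusted p = 3.6e-12). Hr3 rose from 11.9 ± 10.3 (SD, n = 4) to 1059 ± 249.5 (adjusted p = 5.8e-07).

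In limma 4810 of 10179 genes passed, 2713 higher and 2097 lower, and 1158 of them changed at least 2-fold, 341 higher and 817 lower. The groups did not overlap for 4447 genes, where chance gives 2.86%. The authors' deposited table lists 5189 gene rows, 2731 higher and 2458 lower. Of the 8 libraries compared Lsp2 was highest in ecd RNAi replicates 3 and 4, and without the 4 libraries rich in fat body transcripts 4123 genes passed.

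The largest rises by the fixed rule included snRNA:U2:34ABa (FBgn0004191, chromosome 2L, 13211925 to 13212116), a gene of the U2 RNA that pairs with the branch point, which averaged 40.3 ± 25.2 (SD, n = 4) with ecd RNAi and stood at 22438, 22690.1, 14529 and 16569.8 in the 4 libraries with added Xrp1 RNAi (adjusted p = 5.4e-10). Reads of this gene are uncertain because U2 genes are near-identical. The segmentation gene ftz (FBgn0001077, chromosome 3R, 6864324 to 6866244) was listed at 0 in every control and ecd RNAi library and at 279.9, 424, 551 and 474 with ecd plus Xrp1 RNAi. Both snRNA:U2:34ABa and ftz were high in this group alone, so their rises do not undo a change seen with ecd RNAi. Whether they follow Xrp1 RNAi or the stock was not tested. CG46321, which lies within the bounds of Hr3, was listed at 0 in every ecd RNAi library and at 167, 204, 109 and 299 with added Xrp1 RNAi. The gene aos returned from a listing at 0 to 299, 326, 285 and 247. CG8620 fell from 2121 ± 568 (SD, n = 4) to 3.61 ± 0.867 (adjusted p = 2.6e-10). Orion was listed at 0 in every library with added Xrp1 RNAi, Tsf3 at 0, 0, 3.07 and 0. CR10102, a pseudogene beside Arc1 whose reads are uncertain for that reason, fell by 8.33 ± 0.89 (adjusted p = 9.3e-06).

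All 10 Xrp1-associated genes fell, and all 10 adjusted over the list alone (camera adjusted p = 2.2e-08, and adjusted p = 0.0760 with an estimated correlation). The list counts Xrp1 itself, the target of the added RNAi, so a fall of that member was built into the design. Of 27 glutathione S-transferase genes 18 fell and 5 rose, and 18 fell and 6 rose adjusted over the list alone (camera adjusted p = 1.3e-04; adjusted p = 0.0760 with an estimated correlation). GstE6 fell from 3131 ± 356 (SD, n = 4) to 34.9 ± 10.3 (adjusted p = 2.9e-10) and GstE11 rose by 0.64 ± 0.09 (adjusted p = 5.4e-05). In the DNA damage list 18 fell and 4 rose of 27, and 19 fell and 4 rose adjusted over the list alone (camera adjusted p = 1.1e-06; adjusted p = 0.396 with an estimated correlation). Its member p53 fell by 1.44 ± 0.06 (adjusted p = 3.3e-09), Gadd45 fell by 1.54 ± 0.20 (adjusted p = 5.0e-05) and Irbp, the fly Ku70, fell by 1.90 ± 0.09 (adjusted p = 4.3e-09). In the JNK list 13 fell and 3 rose of 21, the same adjusted over the list alone (camera adjusted p = 1.9e-04; adjusted p = 0.570 with an estimated correlation). Mmp1 fell by 1.41 ± 0.15 (adjusted p = 7.3e-06). The call of puc, with a change of -0.39 and adjusted p = 0.0357, ended without ecd RNAi replicate 1, 2 or 4, without ecd plus Xrp1 RNAi replicate 1 or 2, or without the 4 libraries rich in fat body transcripts, with adjusted p of 0.0544 to 0.110 there and 3.3e-03 to 0.110 over all alternatives. Of 11 JAK/STAT genes 8 fell, and 9 adjusted over the list alone (camera adjusted p = 8.0e-06; adjusted p = 0.250 with an estimated correlation). upd2 fell by 5.25 ± 0.39 (adjusted p = 3.8e-07). Of 10 innate immunity genes 5 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.0489; adjusted p = 0.575 with an estimated correlation). Dif fell by 4.36 ± 0.26 (adjusted p = 4.5e-08). The apoptosis genes rpr fell by 1.05 ± 0.10 (adjusted p = 3.3e-06) and hid fell by 0.53 ± 0.08 (adjusted p = 9.0e-05), in a list with 5 that fell and 4 that rose of 14 (camera adjusted p = 0.301).

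All 32 proteasome genes rose, and all 32 adjusted over the list alone (camera adjusted p = 2.7e-13; adjusted p = 0.570 with an estimated correlation). Rpn12 rose from 1807 ± 226 (SD, n = 4) to 3151 ± 157 (adjusted p = 9.3e-06). Of 33 oxidative phosphorylation genes 28 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 3.1e-07; adjusted p = 0.575 with an estimated correlation). Of 20 unfolded protein response genes 14 rose and 1 fell, and 15 rose and 1 fell adjusted over the list alone (camera adjusted p = 4.8e-05; adjusted p = 0.575 with an estimated correlation). Pdi rose by 1.10 ± 0.12 (adjusted p = 1.1e-05). Of 20 heat shock genes 13 rose and 0 fell, and 16 rose adjusted over the list alone (camera adjusted p = 4.4e-04; adjusted p = 0.616 with an estimated correlation). Copies of Hsp70 among them are near-identical, and their separate values are uncertain. Of 45 spliceosome genes 33 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 5.5e-06; adjusted p = 0.575 with an estimated correlation). Prp31 fell by 0.85 ± 0.07 and Brr2 fell by 0.63 ± 0.07 (adjusted p = 6.3e-07 and 1.5e-05). Prp8 rose by 0.31 ± 0.08 (adjusted p = 0.00512). The call ended at 0.24 without the 4 libraries rich in fat body transcripts, with adjusted p = 0.0558 in a range of 3.9e-04 to 0.0558 over the alternatives. Of 40 cell cycle genes 21 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 7.0e-04; adjusted p = 0.662 with an estimated correlation), Mcm7 and Cdk1 among those that rose (adjusted p = 1.5e-04 and 6.1e-05). Of 79 ribosomal protein genes 8 fell and 0 rose, and 1 fell adjusted over the list alone (camera adjusted p = 4.7e-03; adjusted p = 0.772 with an estimated correlation).

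Of 12 wing pouch markers 7 rose and 0 fell (camera adjusted p = 6.6e-03; adjusted p = 0.575 with an estimated correlation). Of 8 notum markers 6 rose and 0 fell (camera adjusted p = 5.2e-03; adjusted p = 0.575 with an estimated correlation). Of 10 muscle precursor markers 8 rose and 0 fell (camera adjusted p = 6.4e-03; adjusted p = 0.396 with an estimated correlation). Each of these lists had the same counts adjusted over the list alone. The limb gene Dll rose by 0.75 ± 0.12, the notum gene pnr by 0.84 ± 0.14 and the muscle precursor gene Him by 1.19 ± 0.18 (adjusted p = 1.8e-04, 2.7e-04 and 1.3e-04). Ecdysone response genes held 10 that rose and 6 that fell of 20, the same adjusted over the list alone (camera adjusted p = 0.186). ImpE2 rose from 3431 ± 2339 (SD, n = 4) to 48850 ± 7472 (adjusted p = 9.5e-05) while ftz-f1 fell by 2.83 ± 0.17 (adjusted p = 3.7e-08). Camera called 16 of 34 lists, 9 higher and 7 lower, and 0 with an estimated correlation. The median, mean and direction of the test differed in sign for the Hippo, hinge, tracheal, neuronal and cytoskeleton lists, none of which passed.

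With the limit on equal ecd RNAi given above, the reversal was counted over the 4867 genes that passed with ecd RNAi against control. Of these, 3899 (80.1%) passed in the opposite direction with ecd plus Xrp1 RNAi against ecd RNAi, made up of 1697 of the 2280 genes that had risen (74.4%) and 2202 of the 2587 that had fallen (85.1%), and 26 moved further the same way. The median gene had 88.5% of its ecd RNAi change removed, at 95.7%, 91.6%, 84.0% and 81.7% in ecd plus Xrp1 RNAi replicates 1 to 4. Among the 1237 genes changed at least 2-fold, 1032 (83.4%) were reversed. Against control 299 of the 4867 genes still differed the same way in the libraries labelled ecd plus Xrp1 RNAi and 39 the opposite way. That comparison called 447 genes in limma and 1093 gene rows in the authors' deposited table, so the 299 depends on the method. A gene that did not pass there is not thereby at the control level. The genes with the largest reversed changes were those named above, such as CG8620, orion, aos and Tsf3. A large change that did not pass as reversed was that of asRNA:CR45139, with 39.3 ± 62.4 (SD, n = 4) in control, 1477 ± 164 with ecd RNAi and 279 ± 99.4 with added Xrp1 RNAi (adjusted p = 0.0761 against ecd RNAi). Pfrx, a fructose bisphosphatase and kinase, did not pass either, with 15.4 ± 30.9 (SD, n = 4), 334 ± 129 and 69.1 ± 30.8 (adjusted p = 0.104). Both passed in a fit of the compared groups alone, with adjusted p of 5.0e-05 and 3.8e-04 in ranges over the alternatives of 5.0e-05 to 0.160 and 3.8e-04 to 0.281.

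Because the ecd RNAi libraries enter both contrasts, they were also split into 2 and 2. Genes were then called on one part and their reversal measured on the other. Of a mean of 4397.5 called genes 72.01% were reversed, at 66.3% to 76.4% over the 6 splits. The median share of the change removed averaged 82.2%, at 66.1% to 92.9% over the splits. In 20 simulations with no reversal 0 genes were reversed and the median share was 2.30%. These drew noise for each gene on its own, without the structure that real libraries share, so the 0 may understate the baseline. Without the 4 libraries rich in fat body transcripts and over the 10179 genes tested with all libraries, 3295 of 4125 called genes were reversed (79.9%), with a median share of 81.4%.

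**Figure D3:**
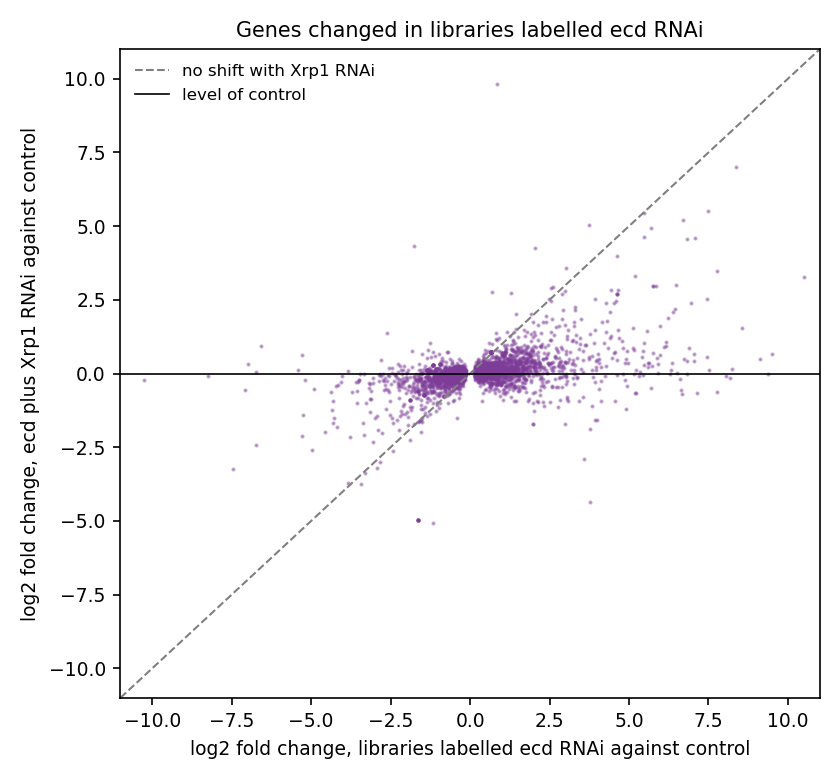
Log2 fold change against control of the 4867 genes that passed with ecd RNAi, with ecd RNAi on the horizontal axis and with ecd plus Xrp1 RNAi on the vertical axis, one point per gene. The dashed line marks no shift between the RNAi groups and the solid line the control level, near which most points lie.

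The libraries labelled ecd plus Xrp1 RNAi were then compared with control. Neither target passed, ecd with a change of 0.22 (adjusted p = 0.183) and Xrp1 with 0.07 ± 0.10 (adjusted p = 0.711), so these values give no check of the label of this group against control. Nor did Irbp18 (0.22, adjusted p = 0.222), Ilp8 (-0.08, adjusted p = 0.925), p53 (0.06, adjusted p = 0.602) or Mmp1 (0.35, adjusted p = 0.196) pass. The cytokine gene upd3 changed by 0.63 (adjusted p = 0.0825) and Gadd45 by 0.61 (adjusted p = 0.113). Both passed in the authors' deposited table, at adjusted p of 0.0324 and 0.0487, while adjusted p over the alternatives ran from 0.0156 to 0.206 for upd3 and from 0.0201 to 0.245 for Gadd45. The temporal transcription factor gene chinmo stayed above control at 1323 ± 281 (SD, n = 4) against 605 ± 57.9 (adjusted p = 0.00249), far under the 16910 ± 4081 of ecd RNAi. GstE1 rose by 1.48 ± 0.12 (adjusted p = 1.8e-05), while GstE8 fell by 0.96 ± 0.14 (adjusted p = 0.00133) and hid fell by 0.43 ± 0.08 (adjusted p = 0.00627).

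In limma 447 of 10179 genes passed, 233 higher and 214 lower, 72 and 50 of them by at least 2-fold. The groups did not overlap for 1718 genes, where chance gives 2.86%, and 2187 genes had an unadjusted p under 0.05. The authors' deposited table lists 1093 gene rows, 496 higher and 597 lower. In limma 1486 genes passed with array weights and 737 under quantile normalization, so the count depends on the method. The count fell to 269, 293 and 265 without control replicate 2, 3 or 4 and to 242 and 269 without ecd plus Xrp1 RNAi replicate 2 or 3. Lsp2 was higher in control replicates 2, 3 and 4 than in every ecd plus Xrp1 RNAi library and lower in control replicate 1, and without the 4 libraries rich in fat body transcripts 474 genes passed, 209 higher and 265 lower, with 295 of them among the 447.

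The largest rise was that of snRNA:U2:34ABa, at 19.95 ± 4.71 (SD, n = 4) in control and 19060 ± 4136 with ecd plus Xrp1 RNAi (adjusted p = 3.7e-09), with the limit on near-identical copies given above. CG44403 was listed at 0 in every control, at 355, 209, 337 and 478 with ecd RNAi and at 149, 139.6, 159 and 78.0 with ecd plus Xrp1 RNAi. CG18853 fell by 5.06 ± 0.31 (adjusted p = 1.7e-06). The histone gene His2B:CG33902, one of many near-identical copies whose reads are uncertain, fell by 7.51 ± 0.63 (adjusted p = 1.8e-05). Of 27 glutathione S-transferase genes 3 fell and 1 rose, and 4 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0112; adjusted p = 0.546 with an estimated correlation). In the JNK list 2 rose of 21, and 6 adjusted over the list alone (camera adjusted p = 3.8e-03; adjusted p = 0.953 with an estimated correlation). Its member puc rose by 0.64 ± 0.14 (adjusted p = 0.0223). The call ended without control replicate 1 or 3, without ecd plus Xrp1 RNAi replicate 2 or 3, or without the 4 libraries rich in fat body transcripts, with adjusted p of 0.0528 to 0.102 there and 3.4e-04 to 0.102 over all alternatives. Of 27 DNA damage genes 2 rose and 1 fell, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0152; adjusted p = 0.953 with an estimated correlation). Ku80, a protein of end joining, rose by 0.49 ± 0.07 (adjusted p = 0.00152). Of 45 spliceosome genes 3 rose and 1 fell, and 6 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0112; adjusted p = 0.953 with an estimated correlation). Prp3 rose by 0.32 ± 0.06 (adjusted p = 0.0120). Of 33 oxidative phosphorylation genes 1 fell, and 1 adjusted over the list alone (camera adjusted p = 0.0112; adjusted p = 0.953 with an estimated correlation), the complex I gene ND-30 with a change of -0.39 (adjusted p = 0.0109).

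No fat body marker of 12 passed in limma, while camera called the list lower (camera adjusted p = 0.0152; adjusted p = 0.953 with an estimated correlation). Camera further called the JAK/STAT, nonsense-mediated decay, cell cycle, Hippo and notum lists higher (camera adjusted p of 9.2e-03, 0.0343, 0.0112, 0.0286 and 0.0359; adjusted p = 0.953 with an estimated correlation for each). It called the ribosomal proteins lower (camera adjusted p = 0.0151; adjusted p = 0.953 with an estimated correlation). In these lists 2 of 11, 1 of 8, 0 of 40, 1 of 15, 0 of 8 and 0 of 79 members passed. Proteasome, unfolded protein response, heat shock and ecdysone lists were not called (camera adjusted p of 0.502, 0.529, 0.181 and 0.502). Of all 34 lists, 8 were called higher and 4 lower, 0 with an estimated correlation, and fry, which asks whether a list's genes move one way, called 1, the glutathione S-transferases. Without the 4 libraries rich in fat body transcripts camera called 3 lists higher and 6 lower, so the balance of these calls turned. In apoptosis genes, rpr changed by -0.46 (adjusted p = 0.0217). The call ended without control replicate 2 or 3, without ecd plus Xrp1 RNAi replicate 1 or 3, or without the 4 libraries rich in fat body transcripts, with adjusted p of 0.0503 to 0.0724 there and 2.2e-03 to 0.0724 over all alternatives. The median, mean and direction of the test differed in sign for the Xrp1-associated, wing pouch and cytoskeleton lists, none of which passed.

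Both RNAi groups were compared with the same 4 control libraries, which by itself makes their fold changes agree across genes. Over the 10179 genes, which are not independent replicates, these changes correlated with Pearson r of 0.389 and Spearman rho of 0.399, against a mean r of 0.488 for simulated unchanged groups set against the same controls. Their covariance was 0.284, against 0.0826 in the simulation, a difference of 0.201. With the controls split into 2 and 2 the mean r was 0.259, at -0.0374 to 0.356 over the splits, and the mean covariance 0.194. Higher calls against control were shared by 173 genes and lower calls by 126. The shared controls raise these overlaps too, and no overlap of unchanged groups was computed.

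Whether introns stayed in transcripts was read from the authors' deposited table of intron retention ratios, which covers 17817 introns and gives group means and adjusted p with no values here that could be tied to single libraries. Ratios are the authors' group means, and the errors between replicates are not known. The authors' deposited table lists 413 introns as changed with ecd RNAi against control, 388 higher in 330 genes and 25 lower, and 412 of them had a mean ratio of at least 0.01. The median ratio of the 388 introns was 0.0545 in control, 0.192 with ecd RNAi and 0.134 with ecd plus Xrp1 RNAi. These introns were chosen for a high ratio with ecd RNAi, which by itself makes the ratio of another group lower, so the medians do not measure an effect of Xrp1 RNAi. Between the RNAi groups 19 of the 388 passed as lower and 0 as higher in the authors' deposited table. Over all introns the mean ratio was 0.119, 0.133 and 0.130 in the 3 groups, and over introns of the table's class clean, with no other feature named over or near them, it was 0.0933, 0.10001 and 0.10004. Introns under 100 nt made up 81.4% of the 388 and 62.7% of all introns, and introns of the class clean 12.9% and 29.4%.

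An intron of Tpi, a glycolytic isomerase (FBgn0086355, intron 1 of 1 transcript, chromosome 3R, 30134095 to 30134250), had ratios of 0.193 in control, 0.703 with ecd RNAi and 0.560 with ecd plus Xrp1 RNAi (authors' deposited table, adjusted p = 5.9e-09 and 3.4e-04 for the RNAi groups against control). In mEFTu1, a mitochondrial elongation factor (FBgn0024556, intron 1 of 1 transcript, chromosome 2R, 13507659 to 13507714), they were 0.164 in control, 0.531 with ecd RNAi and 0.424 with ecd plus Xrp1 RNAi (authors' deposited table, adjusted p = 2.0e-15 and 1.0e-07). The first intron of the ubiquitin ligase gene Cul2 (FBgn0032956, intron 1 of 1 transcript, chromosome 2L, 21658962 to 21659094) had ratios of 0.472 in control, 0.934 with ecd RNAi and 0.563 with ecd plus Xrp1 RNAi, and passed as lower between the RNAi groups in the authors' deposited table (adjusted p = 1.6e-31). So did the intron of the isocitrate dehydrogenase gene Idh (FBgn0001248, intron 1 of 1 transcript, chromosome 3L, 8358716 to 8358849), at 0.292 in control, 0.733 with ecd RNAi and 0.324 with ecd plus Xrp1 RNAi (authors' deposited table, adjusted p = 5.1e-08). An intron of p53 (FBgn0039044, intron 2 of 1 transcript, chromosome 3R, 23053049 to 23053118) passed likewise and stood at 0.0325 in control, 0.351 with ecd RNAi and 0.0463 with ecd plus Xrp1 RNAi (authors' deposited table, adjusted p = 1.7e-04). An intron of MRP, an ABC transporter gene (FBgn0032456, intron 1 of 1 transcript, chromosome 2L, 12719241 to 12722354), went the other way, at 0.793 in control, 0.204 with ecd RNAi and 0.752 with ecd plus Xrp1 RNAi (authors' deposited table, adjusted p = 7.0e-21 and 1.9e-17). None of the introns named here and below is in the table's class clean. Their classes name a known exon, or a feature of the other strand over or near the intron, so reads of other transcripts can enter these ratios.

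With ecd plus Xrp1 RNAi against control the authors' deposited table lists 224 introns, 212 higher and 12 lower, and between the RNAi groups 37, 14 higher and 23 lower. The 212 introns had median ratios of 0.0509, 0.161 and 0.183 in the 3 groups, and 121 of them were also among the 388. Both lists were called against the same controls, which raises their overlap, and no value for unchanged groups is known here. An intron of DCTN3-p24, a dynactin subunit gene (FBgn0010622, intron 1 of 1 transcript, chromosome 2R, 23061595 to 23061682), had ratios of 0.493 in control, 0.558 with ecd RNAi and 0.938 with ecd plus Xrp1 RNAi (authors' deposited table, adjusted p = 1.0e-07 against control). Genes that held an intron from the 388 were more often lower in expression with ecd RNAi, at 162 of 327 (49.5%) against 31.3% of the other genes in both tables (Fisher's exact test, two-sided, odds ratio 2.16, p = 5.4e-11). By the same exact test they were not more often higher, at 65 (19.9% against 23.7%, odds ratio 0.801, p = 0.135). For introns whose ratio rose by at least 0.1, the odds ratio for lower genes was 1.497 (Fisher's exact test, two-sided, p = 0.00892). A retention ratio commonly sets intron reads against spliced reads, so a fall of the spliced transcript can raise it by itself, and part of this association can be built in. Genes are not independent replicates, and both tables come from the same libraries.

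**Figure D4:**
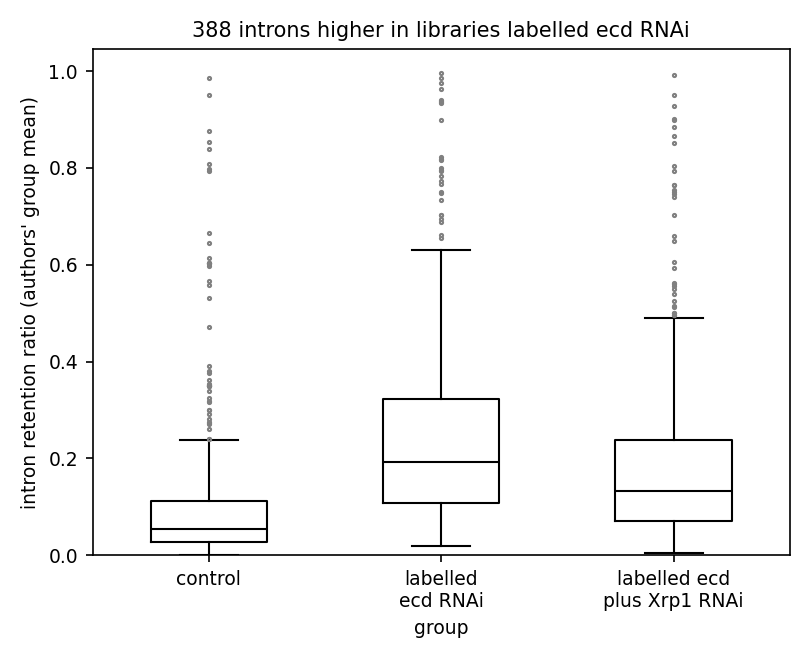
Authors' group mean retention ratio of the 388 introns higher with ecd RNAi, as box plots per group (line, median; box, quartiles). The median is 0.0545 in control, 0.192 with ecd RNAi and 0.134 with ecd plus Xrp1 RNAi.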

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

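The tests on copia copies, on the median of all genes, on copia between the RNAi groups, on the ratio of Fbp1 to Lsp2 and on gene families were chosen only after the result was seen, as were leaving out the 4 libraries rich in fat body transcripts and the count of splits that part every pair.

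Transposable element rows, which the gene tests leave out, stood high in the libraries labelled ecd RNAi. They took 6.65 ± 0.879% (SD, n = 4) of the signal there, against 0.483 ± 0.0345% in control and 0.613 ± 0.0460% with ecd plus Xrp1 RNAi. Summed over its 39 rows the retrotransposon copia averaged 16160.1 ± 1821 normalized counts in control, 1544548 ± 319183 with ecd RNAi and 37087 ± 10837 with ecd plus Xrp1 RNAi, and flea averaged 6455 ± 508, 369869 ± 53243 and 12917 ± 284. The elements invader4 and accord averaged 80148 and 2676 with ecd RNAi, against 679 and 6.90 in control. Of 85 families 45 were higher and 6 lower with ecd RNAi against control in limma, 11 of them at least 4-fold higher, while 30 were lower and 9 higher with ecd plus Xrp1 RNAi against ecd RNAi. With ecd plus Xrp1 RNAi against control 28 were higher, 3 of them at least 4-fold, and 5 lower. The element gypsy was lower with ecd RNAi (log2 fold change -0.72, adjusted p = 0.00784).

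Reads shared between near-identical copies could not make this pattern alone, since the sum over all copia rows rose by 6.56 on the log2 scale with an SE of 0.20. The median log2 fold change of all tested genes was -0.0422, so genes were not raised as a whole. The normalization itself holds this median near 0, so it cannot test a fault of the normalization. Genomic copies carried by one stock stay open: the copia sum changed by -5.40 between the RNAi groups, both labelled with the ecd transgene, but copies elsewhere in the genome were not measured. Activation of some retrotransposons with ecd RNAi, lower when Xrp1 RNAi is added, may be a biological candidate. It was not tested and cannot be told apart from such copies here.

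Of 20 ecdysone response genes 10 fell and 6 rose in the libraries labelled ecd RNAi. Fat body transcripts, which carry their own hormone response, varied between libraries. Without the 4 libraries rich in these transcripts the 10 fallen genes had a median log2 fold change of -2.76, all 10 below 0. They were chosen for their fall in a fit that shares libraries, so the negative sign is partly built in. Eip75B no longer passed (limma, adjusted p = 0.0743). The size of the median is raised by that choice too, and control replicate 2, with Lsp2 at 1594, stayed in. A median this far below 0 still argues against fat body tissue of the 4 left-out libraries as the only cause. A lower hormone signal in the whole larva may be a cause and stays open. The ratio of Fbp1, an ecdysone-induced fat body gene, to Lsp2 was 0.172 to 0.383 with ecd RNAi and 1.14 to 2.08 in control, below every control (exact permutation test, two-sided, p = 0.0286, the smallest that 70 assignments can give). These genes were chosen after their values were seen, so this p restates the values and does not test that explanation. The ratio was 0.363 to 0.950 with ecd plus Xrp1 RNAi, also under every control. Ilp8, which delays the hormone pulse, is a candidate link that was not tested. With ecd plus Xrp1 RNAi against control Ilp8 did not pass, and of 20 ecdysone response genes 1 rose and 0 fell. The low ratio in that group thus stood without a called change of Ilp8 or a called fall of ecdysone response genes.

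With ecd plus Xrp1 RNAi against control, 109 genes passed that did not pass with ecd RNAi against control, 50 higher and 59 lower. Of them 9 (8.26%) are histone or small RNA genes or have an identical copy, so most lie outside these families. The share over all tested genes was not computed, so reads shared within gene families stay open for a part of the set. Without the 4 libraries 88 (80.7%) kept their direction and either passed or held most of their size. They were called in a fit that shares the libraries left, so this share is partly built in. Control replicate 2, with Lsp2 at 1594 against 455 to 833 with ecd plus Xrp1 RNAi, also stayed in. Fat body tissue in some controls thus stays open. Genetic background around the transgenes stays open: of 102 with a position and no identical copy, 4.90% lay next to another such gene, against a mean of 2.00% and an upper bound of 5.88% in 10000 random sets (permutation p = 0.084). By the bound written before that result was seen, such a share would exclude this background. That bound was wrong for a set this small, where the random sets reach above 2 times their mean, so the test could miss such a background. An effect of Xrp1 RNAi that is independent of ecd may be another candidate, untested because no group with Xrp1 RNAi alone was analysed here.

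The number of genes changed was compared with that of other splits of the same 8 libraries into 4 and 4, with a fit of those libraries alone. For ecd RNAi against control the real split gave 4647 genes and the highest of the others 612, so 1 of 35 splits, the real one, gave as many. The split with 612 genes set replicates 1 and 2 of both groups against replicates 3 and 4 and so follows a structure of the samples that fat body transcripts share; within replicates 1 and 2 the comparison gave 4451 genes and within 3 and 4 it gave 3267. For ecd plus Xrp1 RNAi the real split gave 4456 genes against ecd RNAi and 637 against control, the highest other split 1 gene in each, and again 1 of 35 splits gave as many. For these 2 counts that share is under 0.05 and the smallest these splits can give. It argues against chance without excluding it, and does not address other differences between the groups. Control and ecd RNAi libraries count as paired by title number under the fixed rule, although each control correlated best with another number of ecd RNAi. Of the 8 splits that part every such pair 1, the real one, gave as many genes and the highest other 0. These 8 are too few for a share under 0.05. The other 27 splits keep at least 1 pair together, that with 612 genes among them.

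Single libraries stood far from the other 3 of their group for 22 of 314 groups of values tested, where chance gives about 1 in 20 for normally distributed values. In ecd plus Xrp1 RNAi replicate 4 these were Prp8 at 15780.4, hid at 3097, Gadd45 at 953 and Corp at 2.41; in replicate 3 Tsf3 at 3.07 and Him at 299; and in replicate 1 CR10102 at 6.84. In ecd RNAi replicate 1 they were Gadd45 at 3751, CG8620 at 2966, sens at 35.7 and bs at 1077, in replicate 2 Hsp70Bbb at 3095, in replicate 3 Him at 80.9, and in replicate 4 CR43482 at 173 and fok at 127. In the controls they were Ets21C at 16.8 in replicate 1, CG46321 at 53.6, asRNA:CR45139 at 132 and snoRNA:Psi28S-2876 at 52.7 in replicate 3, and CR10102 at 11.2, CG45086 at 2.57 and Pfrx at 61.8 in replicate 4. A group with 3 libraries at 0 and the other above 0 is always counted, however small that value. Tsf3 at 3.07, Corp at 2.41 and CG45086 at 2.57 are such cases, and the 1 in 20 does not hold for them.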

How the results depend on the processing

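The fits without the 4 libraries rich in fat body transcripts, with all rows, without identical copies and of replicates 1 and 2 or 3 and 4 alone were chosen only after the result was seen; the others were planned.

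Requiring a 2-fold change left 1237, 1158 and 122 genes for ecd RNAi against control, ecd plus Xrp1 RNAi against ecd RNAi, and ecd plus Xrp1 RNAi against control, because the threshold is stricter. The first 2 counts stayed within 1.5 times under every other alternative, at 4429 to 4770 and 4280 to 4921 when a library was left out. The last, 447, was 737 under quantile normalization, 1486 with array weights, 1093 by the authors' deposited adjusted p and 242 to 431 when a library was left out. The cause was not tested. The share of higher genes among the calls moved by more than 10 percentage points only with the 2-fold minimum.

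Camera with an estimated correlation called 0 lists in each comparison. The test fry, which does not compare a list with other genes, called 23 with ecd RNAi against control and 1 with ecd plus Xrp1 RNAi against control. The median share of reversal was 81.4% without the 4 libraries, and the correlation of fold changes was 0.259 with the controls split into 2 and 2, which removes the shared controls. The difference in mean intron retention, 0.0136, -0.00252 and 0.0110 for the comparisons in the order above, was 0.0107, -0.00195 and 0.00872 as a median over introns and 0.0160, -0.00267 and 0.0133 for introns with a mean ratio of at least 0.05. These have no test.

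For single genes only values that did not pass changed sign. The gene ecd did between the RNAi groups, at -0.0670 without the 4 libraries. Xrp1 did with ecd plus Xrp1 RNAi against control, at -0.00667 with array weights and -0.0191 to 0.13 when a library was left out. Ilp8 did in the same comparison, at 0.39 under quantile normalization, 0.66 without the 4 libraries and -0.48 to 0.17 when a library was left out, and CG45086 between the RNAi groups, at -2.71 to 0.0168 when a library was left out. Over 170 gene results, leaving out a library kept the call and direction in 1309 refits, ended the call in 44 and gave one in 2, and other settings kept it in 2642, ended it in 32 and gave it in 18.

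With the title number as a replicate block 4865, 4868 and 429 genes passed in the 3 comparisons and 14, 16 and 12 lists were called, so the block moved no count by 1.5 times. With a block by the number in the description, 5127, 5024 and 547 genes passed at a consensus correlation of 0.144. Between the groups that are not paired by title number, the correlations were -0.13, -0.33, -0.27 and -0.15 for control and ecd plus Xrp1 RNAi and -0.17, -0.35, -0.20 and -0.33 for the RNAi groups. For introns, no paired analysis was possible because the intron table's values could not be tied to single samples. Its planned tests per sample, with another transform, a block, the compared groups alone, each library left out and a permutation test of the mean ratio, were not run for the same reason.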

Other observations

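The test over chromosome arms was chosen only after the result was seen.

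Further genes of the lists and 1 retrotransposon are described here. The retrotransposon invader6 averaged 74.3 ± 17.4 (SD, n = 4) in control, 413 ± 138 with ecd RNAi and 1032 ± 125 with ecd plus Xrp1 RNAi, higher again with added Xrp1 RNAi (log2 fold change 1.37, adjusted p = 2.9e-04). The NF-kappaB gene Rel averaged 462 ± 26.8, 979 ± 63.8 and 744 ± 109.7 and stayed above control with added Xrp1 RNAi (log2 fold change 0.68, adjusted p = 0.00124), and mspo, a secreted protein gene, averaged 26.4 ± 5.98, 109 ± 16.99 and 65.8 ± 8.24 (log2 fold change 1.31 against control, adjusted p = 0.00356). The ribosome biogenesis gene Non1 rose by 1.41 ± 0.07 with ecd RNAi (adjusted p = 5.2e-09) and the protease inhibitor gene Ppn, of the basement membrane, fell by 1.58 ± 0.11 (adjusted p = 1.7e-07).

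The 109 genes that passed with ecd plus Xrp1 RNAi and not with ecd RNAi against control lay more densely on one arm. On chromosome 3L they were 35 of 1950 tested genes with no identical copy (1.79%), and 0.663% to 0.969% on the other main arms. A highest share this large was rare in 10000 random sets (permutation p = 0.0022), but the shares had been seen before this test was chosen, so it restates them. A genetic background that differs on that arm may be a cause and stays open. Where the transgenes lie in the genome is not given in the sources used here.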
